A study of Solanum lycopersicum with 8 samples.

How the data were processed

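Root RNA was measured on Affymetrix tomato arrays in 4 groups of 2 arrays: mock-treated and infected roots of the variety Moneymaker, and mock-treated and infected roots of the variety Mogeor. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a NucleoSpin RNA Plant kit and labelled with biotin in a one-cycle reaction. The labels do not say whether the arrays of a group came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

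The deposited values are linear intensity values, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. No version of MAS5 is given, and the deposited values hold no detection calls. The table held 10209 probe sets on 8 arrays, all 81672 values were above 0, and the mean of each array after leaving out the lowest and highest 2% of values was 500.4 or 500.5, so the arrays were already scaled to a common mean. Such scaling fixes the mean signal of each array and leaves its median free to move with the shape of the distribution. No replicate pair held identical columns.

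From the deposited intensities, log2(signal + 16) was computed without further normalization between arrays. A fold change on this scale understates the change of dim probe sets. The 108 AFFX control probe sets were left out, then the 25% of probe sets with the lowest mean over all arrays (mean log2 value up to 5.71). None of the 63 reporter probe sets was above that bound, and 7575 probe sets were tested. limma 3.58.1 in R 4.3.3 fitted the 4 groups together with lmFit and eBayes with a trend, so that all groups shared 1 estimate of the spread (4 residual and 3.95 prior degrees of freedom). The 6 comparisons were infection in each genotype, infection averaged over both genotypes, the genotype difference in mock-treated and in infected roots, and the interaction. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set passed at an adjusted p of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

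Genes were named from the platform annotation, updated by gene ID through a RefSeq gene table of the assembly SLM_r2.1. Of the 10209 probe sets, 909 had 1 gene symbol, 0 had several and 9300 were not listed; 885 of the 909 matched the RefSeq table. Among the tested probe sets 688 (9.08%) had a name, for 638 genes, so most of the changes described by counts belong to probe sets without a name here.

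The named genes followed a rule fixed before the data were examined. In each comparison these were the 10 highest and 10 lowest log2 changes among genes past the threshold whose array values did not overlap between the groups (within each genotype for the averaged effect), plus up to 4 members of each gene list past the threshold. Where fewer than 5 passed in a direction, up to 5 genes with the smallest unadjusted p were taken, as values that did not pass. A gene with several probe sets was represented by the one with the smallest p among the named genes. Of the 16 gene lists, matched by symbol only because neither table holds descriptions, 13 had at least 5 measured genes. These 13 were tested with limma's camera (preset correlation 0.01, 1 probe set per gene, the one with the highest mean). Their members were also adjusted over each list alone. That adjustment does not reach across lists or comparisons, so the calls made this way have no shared error control. The lists were pathogenesis-related proteins, jasmonate synthesis and wound response, ethylene synthesis and response, phenylpropanoid and lignin synthesis, peroxidases and redox enzymes, isoprenoid synthesis, defence signalling, cell wall, photosynthesis as markers of shoot tissue, cytosolic ribosomal proteins, heat shock proteins, nutrient and water transport, histones with cyclins and tubulins, auxin, fermentation with sucrose breakdown, and abscisic acid with dehydration and lipid transfer. The symbol patterns also took AGP-S2, AgpL1 and AGPL3, subunits of ADP-glucose pyrophosphorylase, into the cell wall list. They took the Rab GTPases Rab11a, Rab1A, RAB1B and Rab1C into the abscisic acid list. Matching by symbol also missed genes, among them the amino acid transporter AAP1 for the transport list and the MAP kinase MAPK10 for defence signalling. Counts of list members hold only for the genes matched.

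The fits were tested on simulated data for 7575 probe sets, with 50 probe sets changed at each fold size. At a 2-fold change 76% were recovered for infection in either genotype, 94% for the averaged effect, 68% for either genotype comparison and 36% for the interaction. At a 1.5-fold change, a size common among the calls reported, 20% and 16% were recovered for infection in Moneymaker and Mogeor, 48% for the averaged effect, 20% and 14% for the genotype difference in mock and infected roots and 10% for the interaction. At a 4-fold change the shares were 100% for all comparisons except the interaction, at 94%. The simulated errors were independent between probe sets, so these shares need not hold for the real arrays. In Mogeor the lowest log2 change was -2.457 and the lowest interaction was -4.033, and neither passed. The number of arrays limits the precision.

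Alternatives fixed before the data were examined were a pseudocount of 1, quantile normalization, median centring, no filter or a filter at 50%, eBayes without trend, the replicate number as a block, fits on only the groups compared, leaving out probe sets with the suffixes _x_at and _s_at, a 2-fold minimum and leaving out each array in turn, and for the lists an estimated correlation, limma's fry and all probe sets in place of 1 per gene. Leaving out an array leaves its group with 1 array, which is then assumed to vary like the other groups. Chosen after seeing the data were 2 covariates, each array's mean log2 ratio of 3′ to 5′ control probe sets and its 25S rRNA control signal, leaving out 2 arrays together, the named genes as the background of the list test, the lists without the misplaced members, and a crossed replicate block. Control probe sets were used only for these 2 covariates and for the array quality values.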

Results

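Transcripts of tomato (Solanum lycopersicum) roots were measured in plants infected with Pyrenochaeta lycopersici, the soil fungus of corky root disease, and in mock-treated plants. The labels describe the variety Moneymaker as susceptible and Mogeor as resistant to this fungus. Each of the 4 combinations of genotype and treatment had 2 arrays. The median signal of an array lay between 163.2 and 193.3, and replicate arrays had Spearman correlations of 0.982 to 0.993 across probe sets. The series asks how roots respond to the fungus, and its design also asks how the varieties differ before and after infection.

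Control probe sets were compared between infected and mock arrays. The mean log2 ratio of 3′ to 5′ probe sets of 5 control transcripts, which is higher when the labelled RNA is shorter, was 0.361 ± 0.058 (SD, n = 2) in Moneymaker mock, 0.942 ± 0.19 in Moneymaker infected, 0.508 ± 0.0778 in Mogeor mock and 0.798 ± 0.169 in Mogeor infected arrays. All 4 infected arrays lay above all 4 mock arrays, with a difference of means of 0.436. The two-sided exact permutation p was 0.0286, the smallest that 70 arrangements allow. Its Benjamini-Hochberg adjusted p over 2 measures was 0.0571, which does not pass. Full separation in 1 measure cannot pass this adjustment unless the other measure passes too, so this outcome says nothing against the difference. The arrangements also exchange arrays across the varieties. Taken singly, the ratios of ef1a and the glutathione transferase separated all infected from all mock arrays. Those of actin, gapdh and ubiquitin overlapped. For actin the ratio was 0.292 on Mogeor infected replicate 1 and 0.331 on Moneymaker mock replicate 2. The 25S rRNA control signal was 1048 ± 10.6 in Moneymaker mock and 2851 ± 402 in Moneymaker infected arrays. In Mogeor it was 2588 ± 1450 in mock and 2681 ± 598 in infected arrays, and infected and mock arrays together did not differ past the threshold (two-sided exact permutation p = 0.143, adjusted p = 0.143). On the first principal component (42.8% of the variance), Mogeor mock replicate 2 and Moneymaker infected replicate 1 lay between the other arrays of the varieties, at 2.0 and -0.3, against 17.7 to 26.6 for the other Moneymaker arrays and -24.9 to -21.0 for the other Mogeor arrays.

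**Figure D1:**
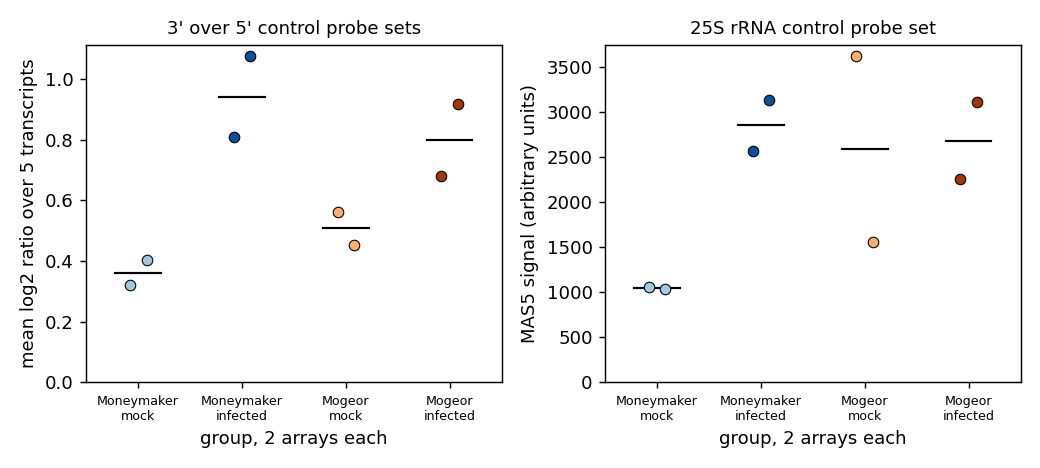
Control probe sets on each array, with the mean log2 ratio of 3′ to 5′ probe sets on the left and the MAS5 signal of the 25S rRNA probe set on the right. Points are the 2 arrays of a group and bars their mean; the infected arrays have the 4 highest ratios, and the 25S signal of Mogeor mock spreads from 1561 to 3616.

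Averaged over both genotypes, infected roots had more transcript of CEVI-1, a peroxidase known from viroid-infected tomato. Its signal was 74.6 ± 35.3 (SD, n = 2) in mock and 186 ± 51.8 in infected Moneymaker roots, and 25.7 ± 17.2 and 177 ± 16 in Mogeor, a log2 rise of 1.73 ± 0.26 (SE; limma adjusted p = 0.0144). Its signal on Mogeor mock replicate 2 lay below that array's highest reporter signal of 23.6, so the size of this change depends on the value added before the logarithm, and no fold is given. The amino acid transporter AAP1 rose 2.01-fold (log2 1.01 ± 0.21, limma adjusted p = 0.0254) and the DNA methyltransferase MET1 1.75-fold (log2 0.81 ± 0.11). The divinyl ether synthase DES, an enzyme of oxylipin synthesis, rose 1.58-fold (log2 0.66 ± 0.16) and SPY, known to restrain gibberellin signalling, 1.54-fold (log2 0.62 ± 0.11). LOC543813, LOC544102, the Mei2-like gene AML1, LOC543912 (synonym ADCS) and LOC543829 also rose, by 1.52-fold to 1.81-fold. With the ratio of 3′ to 5′ control probe sets as a covariate, DES and LOC543813 turned direction, to log2 values of -0.073 and -0.21. Among the genes that fell were adc1 (2.51-fold lower, log2 -1.33 ± 0.19), CIP1 (2.41-fold), LOC543703 (2.14-fold) and BMY3 (2.08-fold). Others that fell were the metallothionein MT4 (1.89-fold, log2 -0.92 ± 0.10, limma adjusted p = 0.0119), LOC544158 (1.72-fold), the ACC synthase ACS1A (1.70-fold), the cryptochrome CRY1A (1.69-fold), BL3 and LOC543663 (both 1.67-fold). All 4 probe sets of MT4 fell, whereas the other probe sets of adc1, CIP1, BMY3, CRY1A, LOC544102 and LOC543663 did not pass. The other 3 of adc1 had log2 values of 0.27 to 0.55, that of LOC544102 had 0.02 and the other 4 of LOC543663 had -0.60 to 0.11. That of CRY1A had 0.22, that of CIP1 -0.16 and those of BMY3 0.15 and -0.11. Of 7575 probe sets 1355 passed, 553 higher and 802 lower, and 86 of them changed at least 2-fold; named genes split the other way, with 77 higher and 28 lower. The share of higher calls was 40.8% as deposited, 52.2% after quantile normalization and 65% after median centring, which moved the median log2 change of all probe sets from -0.0375 to 0.0819.

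Of 34 measured genes of ethylene synthesis and response, 8 rose, 1 fell and 25 did not pass in the averaged comparison; adjusted over the list alone, 9 rose and 1 fell. Those that rose include CTR3 (log2 0.52 ± 0.10), a Raf-like kinase of the ethylene pathway, the ethylene-responsive genes ER49 (0.45 ± 0.10) and ER66 (0.57 ± 0.13), and the transcription factor JERF1 (0.46 ± 0.11). The other 4, named after their values were seen, were CTR1, CTR4, EIL3 and EIN2 (0.77 ± 0.21). The gene that fell was ACS1A, which makes the ethylene precursor. The list lay above the other probe sets (camera adjusted p = 0.00158), with adjusted p = 0.499 with an estimated correlation and adjusted p = 0.307 against named genes only. The list test takes only transcript levels, so it does not show whether ethylene signalling was more active. Of 17 defence signalling genes 2 rose, the transcription factor WRKY2 (log2 0.48 ± 0.11) and the MAP kinase kinase MKK2 (0.36 ± 0.09), also when adjusted over the list alone, and 15 did not pass (camera adjusted p = 0.00653; adjusted p = 0.499 with an estimated correlation; adjusted p = 0.307 against named genes only). The ethylene and defence lists share PTI4, PTI5 and PTI6, so their results are not separate in any comparison. Named probe sets as a whole had a median log2 change of 0.118 against -0.0548 for unnamed ones. They were brighter, with a median log2 signal of 8.97 against 8.34. The ratio of 3′ to 5′ control probe sets was also higher in infected arrays, and with it as a covariate both lists turned direction (adjusted p = 0.552 and 0.0953). Adjusted p ranged from 0.000166 to 0.552 for ethylene and from 0.00101 to 0.499 for defence over 16 alternatives. After quantile normalization 9 ethylene genes were higher and 2 lower, and after median centring 12 and 0.

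No other list passed camera in the averaged comparison. Among 10 pathogenesis-related genes none rose and TSI-1 fell (log2 -0.60 ± 0.12); PR-P2 and P4 had values of 1.01 ± 0.34 and 0.96 ± 0.41 that did not pass, and 9 of the 10 genes had values above 0. Of 12 jasmonate and wound-response genes 1 rose and 1 fell, which were the 12-oxophytodienoate reductases OPR3 (0.42 ± 0.11; -0.008 with the control ratio as a covariate) and opr2 (-0.53 ± 0.10). Of 7 phenylpropanoid genes hqt, the chlorogenic acid enzyme, rose (0.37 ± 0.11), and the peroxidase TPX2 (-0.48 ± 0.11) and the tyramine hydroxycinnamoyltransferase THT7-8 (-0.56 ± 0.13) fell. Of 13 peroxidases and redox enzymes CEVI-1 and the catalase cat1 (0.63 ± 0.18) rose and TPX2 fell. Among 30 cell wall genes the beta-galactosidase TBG5 rose (0.50 ± 0.11), and XTH16 fell by 1 probe set (-0.61 ± 0.16) that was not the one standing for it in the list. The median of this list was -0.0464 although camera placed it above the other probe sets, and was 0.12 after quantile normalization and 0.073 after median centring. The plasma membrane proton pump LHA1 (0.52 ± 0.09) was the 1 of 14 listed transport genes that rose, in a list that does not hold AAP1. The histone H1 (0.38 ± 0.08) was the 1 of 13 in its list, although its other probe set had a value of -0.03, and the sucrose synthase sus3 (0.37 ± 0.10) was the 1 of 5 fermentation genes. IAA16 was the 1 of 6 auxin genes that fell (-0.66 ± 0.19). Adjusted over the list alone, COI1 among the jasmonate genes (0.37 ± 0.11), THT1-3 among the phenylpropanoid genes (-0.46 ± 0.15) and IAA3 among the auxin genes (-0.58 ± 0.19) passed as well. None of 5 ribosomal or 8 abscisic acid genes passed. Of 4 heat shock genes, too few for camera, HSC80 (0.33 ± 0.08) and Hsp90-1 (0.42 ± 0.11) rose. The arrays of infected and mock roots overlapped for cat1 and Hsp90-1. The 4 photosynthesis genes, listed as markers of shoot tissue, did not pass and had a median of -0.0465. Their mean log2 signals were 11.2 for PSBO, 10.6 for PSBR, 7.36 for PETE and 6.27 for CAB4. Unchanged values do not show that shoot tissue was absent. Neither of the 2 isoprenoid genes passed, with a median of 0.22.

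With the ratio of 3′ to 5′ control probe sets as a covariate, or with the 25S rRNA signal, 0 probe sets passed in the averaged comparison in limma, with 423 and 1009 at an unadjusted p under 0.05. The count was 1 without both Moneymaker infected replicate 1 and Mogeor mock replicate 2. Leaving out single arrays gave 0 calls without Moneymaker mock replicate 1 (limma, 1921 at an unadjusted p under 0.05), 1 without Moneymaker mock replicate 2, 651 and 442 without Moneymaker infected replicate 1 and replicate 2, 75 without Mogeor infected replicate 2 and 244 without Mogeor mock replicate 2. It gave 1443 without Mogeor infected replicate 1 and 1552 without Mogeor mock replicate 1.

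In Moneymaker alone, MET1 was 2.06-fold higher in infected roots (log2 1.04 ± 0.15, SE; limma adjusted p = 0.0369), from a signal of 107 ± 4.19 (SD, n = 2) to 237 ± 22.1. LOC544102 (1.87-fold), AML1 (1.84-fold), SPY (1.77-fold), the MADS-box gene TDR6 (1.74-fold), the glutathione synthetase GSH2 (1.58-fold) and the MAP kinase MAPK10 (1.5-fold) also rose. LOC543703 was 2.84-fold lower, adc1 2.78-fold, LOC543663 1.95-fold, TPX2 1.82-fold (log2 -0.86 ± 0.15, limma adjusted p = 0.0382), MT4 1.75-fold, TPSI1, a gene known from phosphate starvation, 1.71-fold, the vacuolar processing enzyme VPE5 1.63-fold, opr2 1.60-fold and the remorin rem-1 1.49-fold. For adc1, MT4, VPE5, LOC543663 and LOC544102 only 1 of the several probe sets passed in Moneymaker. The other probe sets of MT4 had log2 values of -1.01 to -0.53 and those of LOC543663 -0.49 to -0.16. Those of adc1 had 0.27 to 0.57, in the other direction. For VPE5 the others had 0.22 and -0.17, and for LOC544102 the other had 0.04. In all, 326 of 7575 probe sets passed, 108 higher and 218 lower (33.1% higher; 48.1% after quantile normalization and 54.4% after median centring), and 129 changed at least 2-fold. Of 2 probe sets without a gene name, picked after their values were seen, one rose 4.42-fold and the other was 6.46-fold lower.

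In Moneymaker, TPX2 was the 1 of 7 phenylpropanoid genes that fell and also the 1 of 13 peroxidases; adjusted over the list alone 3 phenylpropanoid genes fell, TPX2, THT7-8 and CCR1. Of 12 jasmonate genes opr2 fell, also when adjusted over the list alone. Ethylene genes, defence signalling genes and histones, cyclins and tubulins lay above the other probe sets as lists (camera adjusted p = 0.041 for each; adjusted p = 0.447 for each with an estimated correlation; adjusted p = 0.695, 0.659 and 0.626 against named genes only), and 0 of their members passed singly, over all probe sets or adjusted over the list alone. With the control ratio as a covariate the ethylene and defence lists turned direction (adjusted p = 0.0765 and 0.0101). Over 16 alternatives adjusted p ranged from 0.00228 to 0.695 for ethylene, from 0.0101 to 0.659 for defence and from 0.0301 to 0.626 for histones, cyclins and tubulins. The ethylene signalling gene EIN2 had a value of 1.11 ± 0.30 that did not pass. None of 10 pathogenesis-related genes passed; PR-P2 had 1.29 ± 0.47, CHI3 1.15 ± 0.46 and the chitinase CHI17 0.76 ± 0.20.

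No probe set passed with the control ratio or the 25S rRNA signal as a covariate (limma, 352 and 618 at an unadjusted p under 0.05), and both moved with infection in Moneymaker. With the control ratio, 318 of the 326 effects had the same direction at a median of 0.725 of their size, and the median SE went from 0.168 to 0.372. The count was 6 and 0 without Moneymaker infected replicate 1 and replicate 2, 0 and 1 without Moneymaker mock replicate 1 and replicate 2 (limma; 1656 and 1083 at an unadjusted p under 0.05 for the counts of 0), 505 and 509 without Mogeor mock replicate 1 and replicate 2, and 23 without Moneymaker infected replicate 1 and Mogeor mock replicate 2 together.

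In Mogeor alone no probe set passed in limma, with 1243 at an unadjusted p under 0.05 where chance gives 379, and a smallest adjusted p of 0.147. The named genes with the smallest p included CEVI-1, whose change has no firm size because its signal on Mogeor mock replicate 2 was not above the reporter probe sets. They also included MAPK10 at a log2 value of 0.48 ± 0.12 (SE), CTR3 at 0.57 ± 0.14, the phospholipase PLDb1 at 0.54 ± 0.14 and LHA1 at 0.52 ± 0.13. Below 0 stood MT4 at -1.04 ± 0.13, the glutathione transferase ctu1 at -0.94 ± 0.17, adc1 at -1.18 ± 0.27, RSI-1 at -1.5 ± 0.34 and PDH at -0.42 ± 0.10. The other 3 probe sets of adc1 had values of 0.25 to 0.52. As lists, ethylene genes (camera adjusted p = 0.000122) and defence signalling genes (camera adjusted p = 0.00139) lay above the other probe sets, with adjusted p = 0.453 for each with an estimated correlation and adjusted p = 0.195 for each against named genes only. Over 16 alternatives adjusted p ranged from 5.75e-06 and 8.04e-05 to 0.827 for both, the last with the control ratio as a covariate, where the defence list turned direction. Adjusted over the list alone, CEVI-1 passed among the peroxidases, hqt (0.48 ± 0.15), THT7-1 (0.36 ± 0.12) and THT1-3 (-0.62 ± 0.21) among the phenylpropanoid genes, TSI-1 (-0.69 ± 0.18) among the pathogenesis-related genes and rpl38 (-0.57 ± 0.16) among the ribosomal ones. The control ratio was higher in the infected Mogeor arrays too, and 9 probe sets passed without Mogeor mock replicate 1.

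The infection effects of the varieties resembled each other. Across 7575 probe sets, which are not independent replicates, the log2 changes in Moneymaker and Mogeor had a Pearson correlation of 0.708 and a Spearman correlation of 0.711, and 77.6% had the same sign; the comparisons share no array. Of the 326 probe sets past the threshold in Moneymaker, 319 had the same sign in Mogeor. Of these, 224 had an unadjusted p under 0.05 there in limma, against 1243 of all 7575 probe sets. Both comparisons use 1 estimate of the spread per probe set. Choosing on Moneymaker favours probe sets with a low estimate, which also lowers their p in Mogeor. The median ratio of the Mogeor to the Moneymaker change was 0.555, and that ratio is lowered by choosing the probe sets on Moneymaker. MET1 had a log2 change of 1.04 in Moneymaker and 0.58 in Mogeor, and MT4 -0.80 and -1.04. With the 25S rRNA signal or the control ratio as a covariate the correlation was 0.36 or 0.786. Both effects then share the error of 1 fitted slope, so these values are no measure of likeness. The control ratio was higher in infected arrays of both varieties, at 0.942 against 0.361 in Moneymaker and 0.798 against 0.508 in Mogeor. The median log2 change rose from the dimmest to the brightest probe sets, -0.148 to 0.083 in Moneymaker and -0.135 to 0.076 in Mogeor. After quantile normalization the correlation was 0.698. A shared difference in RNA integrity could also give such likeness, so the likeness alone does not show a shared response to the fungus.

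**Figure D2:**
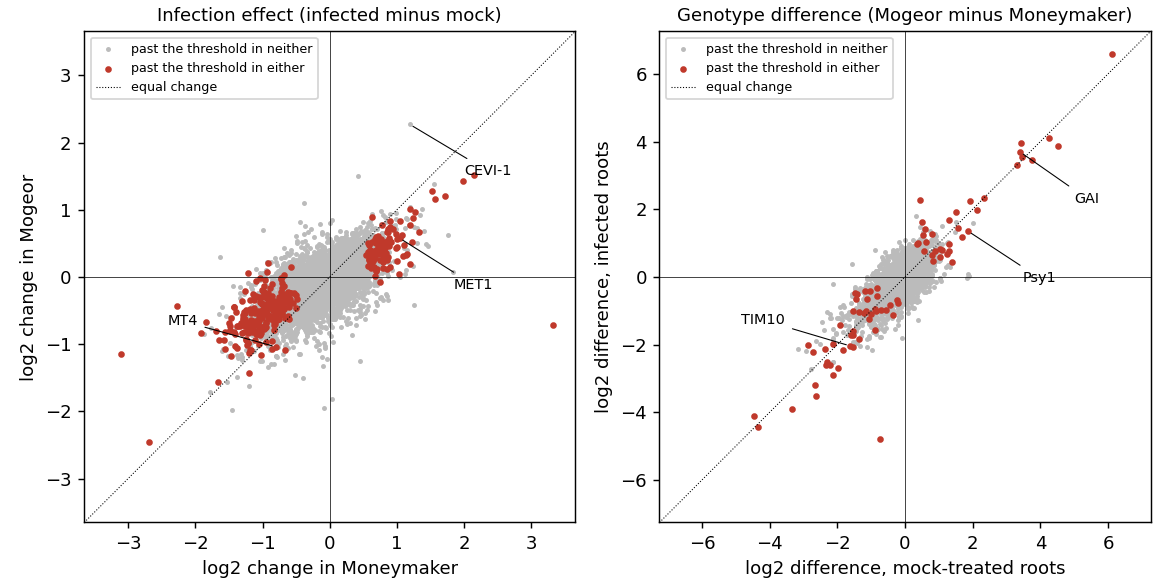
Log2 changes of 7575 probe sets on infection in Moneymaker against Mogeor (left) and log2 differences between the varieties in mock-treated against infected roots (right). Red points passed an adjusted p of 0.05 in either of the 2 comparisons of a panel and the dotted line marks equal change; the correlations are 0.708 and 0.739.

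The interaction asked whether infection acted differently in the varieties. No probe set passed in limma; 245 had an unadjusted p under 0.05, fewer than the 379 that chance gives, and the smallest adjusted p was 0.999. The named genes with the smallest p, none of which passed, include TPX2, with infection effects of -0.86 in Moneymaker and -0.10 in Mogeor (difference 0.77 ± 0.21), rem-1, with -0.57 and 0.15 (difference 0.72 ± 0.17), and CHI17, with 0.76 and -0.30 (difference -1.06 ± 0.29). SPE4, LOC543937 and LOC543896 had differences of 1.03 ± 0.27 (-0.39 in Moneymaker, 0.64 in Mogeor), 0.52 ± 0.14 (-0.21, 0.30) and 0.94 ± 0.29 (-0.15, 0.79). PDH, TPRP-F1, LOC543968 and TDR6 had -0.56 ± 0.15 (0.14, -0.42), -1.14 ± 0.36 (0.86, -0.28), -0.75 ± 0.26 (0.48, -0.27) and -0.67 ± 0.24 (0.80, 0.13). The 7 phenylpropanoid genes lay higher in Mogeor than in Moneymaker in their infection effect as a list (median difference 0.206, camera adjusted p = 0.0449). The camera adjusted p was 0.402 with an estimated correlation and ranged from 0.00131 to 0.402 over 16 alternatives. No member passed over all probe sets, and 2 were higher when adjusted over the list alone. The interaction equals the genotype difference in infected roots less that in mock-treated roots. For this list those differences had medians of -0.125 (camera adjusted p = 0.527) and -0.331 (camera adjusted p = 0.0133). The interaction and the mock-treated difference rest on the same mock arrays, so they are not separate results.

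In mock-treated roots, Mogeor had 10.6-fold more signal than Moneymaker for GAI, the DELLA protein that represses gibberellin responses and is also called PROCERA. The signal was 660 ± 67.5 (SD, n = 2) in Mogeor and 47.7 ± 6.05 in Moneymaker, a log2 difference of 3.41 ± 0.17 (SE; limma adjusted p = 6.69e-05), measured by 1 probe set. Psy1, a phytoene synthase of carotenoid synthesis, was 3.65-fold higher (log2 1.87 ± 0.19, limma adjusted p = 0.00404) by 1 probe set, while its other one had a value of 0.00. The cyclin-dependent kinase inhibitor krp2 was 2.47-fold and CIF1, a cell wall invertase inhibitor, 1.75-fold higher. Lower in Mogeor were the extensin ext1 (3.78-fold, log2 -1.92 ± 0.28), TIM10 of mitochondrial protein import (3.10-fold), TPX2 (2.25-fold) and LOC543607, also called ctu2 (2.04-fold). In total 61 of 7575 probe sets passed, 26 higher and 35 lower in Mogeor, and 54 differed at least 2-fold. Of 4 probe sets without a gene name, picked after their values were seen, 1 was 22.7-fold higher and 1 was 20.3-fold lower in Mogeor. The others had signals of 2217 ± 650 in Mogeor against 15.4 ± 1.05 in Moneymaker, and of 20.8 ± 0.146 against 792 ± 31.4 (SD, n = 2). The signal of 15.4 is within those of the reporter probe sets. That of 20.8 is close to the highest reporter signals of Mogeor mock replicate 1 and replicate 2, 18.8 and 23.6. No fold is given for these probe sets.

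Phenylpropanoid genes lay lower in Mogeor mock-treated roots as a list (median log2 -0.331; camera adjusted p = 0.0133; adjusted p = 0.36 with an estimated correlation; adjusted p = 0.0764 against named genes only; 0.00202 to 0.36 over 16 alternatives). TPX2 was the 1 of 7 that passed; adjusted over the list alone THT7-1 (-0.50 ± 0.12) passed too. No other list passed. Of single members, ext1 was the 1 of 30 cell wall genes and krp2 the 1 of 13 histone, cyclin and tubulin genes past the threshold. Adjusted over the list alone, opr2 (0.50 ± 0.14) and RAB1B (0.35 ± 0.11) were higher, and AOC (-1.09 ± 0.24), IAA17 (-1.39 ± 0.28), Wiv-1 (-0.86 ± 0.21), LEA14 (-1.28 ± 0.41) and NCED1 lower. Among values that did not pass, NCED1, the 9-cis-epoxycarotenoid dioxygenase of abscisic acid synthesis, stood at -2.13 ± 0.40, AGAL at -1.36 ± 0.24, rem-1 at -0.64 ± 0.12, LOC543937 at -0.52 ± 0.10 and T12 at -0.67 ± 0.13. Above 0 stood the ferric reductase FRO1 at 1.34 ± 0.35, LOC543971 at 1.03 ± 0.18, ail at 0.97 ± 0.19, NHX1 at 0.93 ± 0.22 and TFT6 at 0.57 ± 0.11. The count was 20 without either Moneymaker mock array, 27 without Mogeor mock replicate 1, 163 without Mogeor mock replicate 2, 33 and 10 with the control ratio and the 25S rRNA signal as covariates, and 320 without Mogeor mock replicate 2 and Moneymaker infected replicate 1 together.

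In infected roots GAI was 12.9-fold higher in Mogeor (signal 855 ± 4.06 against 52 ± 10.5, SD, n = 2; log2 3.69 ± 0.17, SE; limma adjusted p = 6.27e-05). Psy1 was 2.54-fold higher by the same probe set, with -0.39 ± 0.19 for the other, and TFT6, a 14-3-3 protein, 1.69-fold higher. TIM10 was 4.10-fold lower (log2 -2.04 ± 0.20, limma adjusted p = 0.00252) and PDH 1.71-fold lower. Of 7575 probe sets 58 passed, 25 higher and 33 lower in Mogeor, and no list passed camera. CHI17 had a value of -1.17 ± 0.20 and an adjusted p of 0.0501 in limma; adjusted over the list alone CHI17 was lower and the chitinase CHI9 (0.47 ± 0.14) higher. Values that did not pass also include opr2 at 0.79 ± 0.14, IAA27 at 0.95 ± 0.17, CIF1 at 0.64 ± 0.12, the phosphate transporter PT2 at 1.52 ± 0.32 and URED at 0.84 ± 0.20. Below 0 stood WRKYIId-4 at -0.76 ± 0.13, ER69 at -0.69 ± 0.12, ext1 at -1.43 ± 0.28 and T12 at -0.68 ± 0.13. Adjusted over the list alone, 4 of 13 genes of the histone, cyclin and tubulin list were lower. These were the cyclin-dependent kinases CDKB1 and CDKB2, the cyclin CycA1 and PCNA. The inhibitors krp1 and krp2 were higher. None of the 13 passed over all probe sets (camera adjusted p = 0.527 for the list). In the other lists opr2, CTR3, ER1, PT2, IAA27 and ADH2 were higher and ER69, WRKYIId-4, ext1, LHA2, IAA17, Wiv-1 and NCED1 lower when adjusted over the list alone. The count was 126 and 29 without Moneymaker infected replicate 1 and replicate 2 and 29 and 25 without Mogeor infected replicate 1 and replicate 2. It was 110 and 109 without Mogeor mock replicate 1 and replicate 2, and 33, 102 and 303 with the control ratio, with the 25S rRNA signal and without the 2 arrays that lay between the varieties.

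The differences between the varieties were alike in both treatments. Probe sets past the threshold in both numbered 16 higher and 22 lower in Mogeor, and 0 went in opposite directions. Independent lists would share 0.0858 and 0.152. These lists are not independent, because both comparisons use 1 estimate of the spread per probe set. The log2 differences had a Pearson correlation of 0.739 and a Spearman correlation of 0.601 across 7575 probe sets, which are not independent replicates, with no array in common. By their place in the SLM_r2.1 gene table, the 8 called genes of mock-treated roots lay on 5 of 12 chromosomes and the 5 of infected roots on 4. No chromosome held more called genes than others past the threshold (two-sided Fisher exact tests, smallest adjusted p = 0.0955 and 0.569), and 0 called genes were neighbours among the 628 placed genes. In mock-treated roots 1 chromosome held 3 of the 8 (smallest unadjusted Fisher exact p = 0.00796). Only 8 of 61 called probe sets in mock-treated and 5 of 58 in infected roots had a name. The tests can therefore not tell whether the calls cluster.

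**Figure D3:**
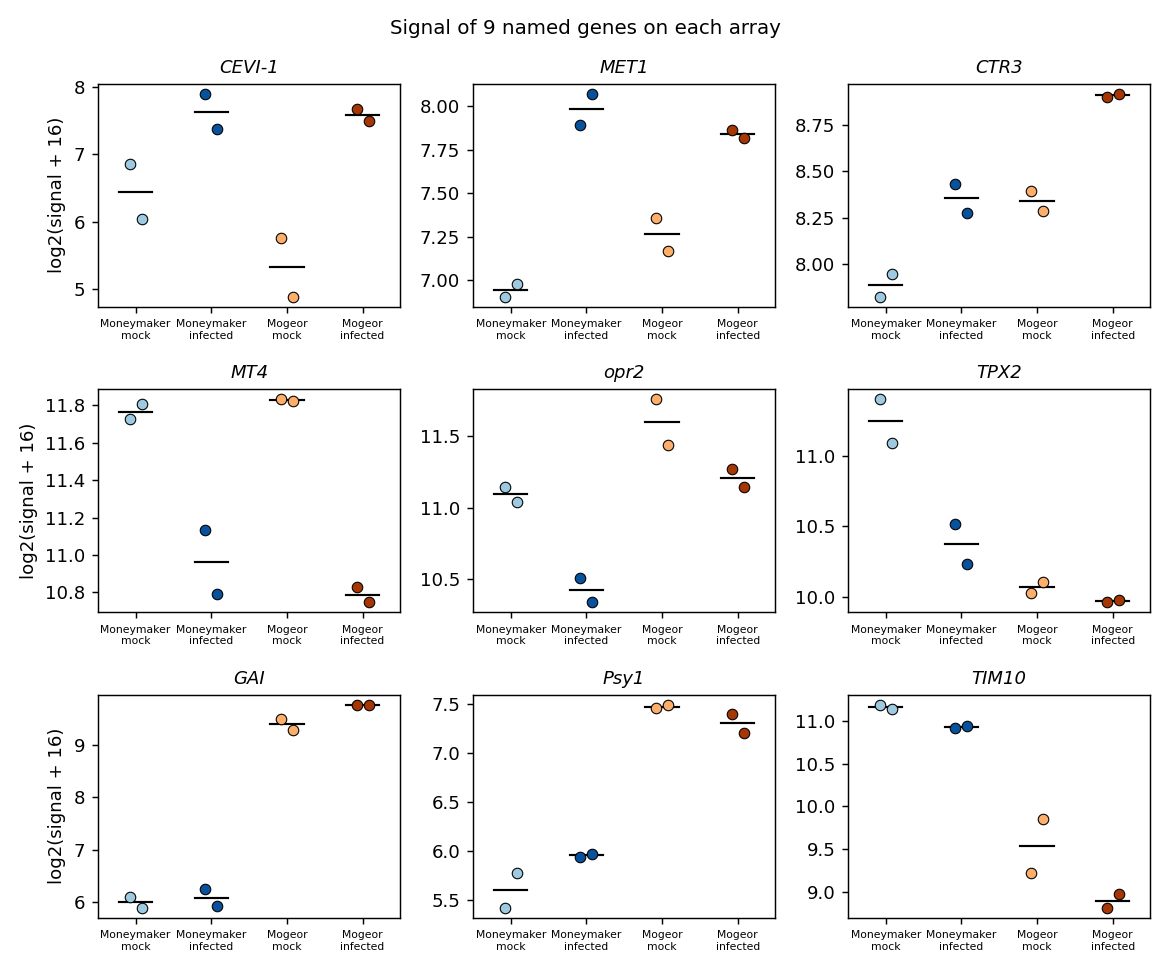
Signal of 9 named genes as log2(signal + 16) on each array, with 2 points per group and a bar for their mean; axes differ between panels and do not start at 0. CEVI-1, MET1 and CTR3 are higher and MT4 and opr2 lower in the infected arrays of both varieties, TPX2 is highest in Moneymaker mock, and GAI, Psy1 and TIM10 separate the varieties in both treatments.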

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

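The tests of RNA integrity and of other splits of the arrays were set before their results were seen; the tests of scale, of neighbouring probe sets and of the arrays between the varieties were chosen only after the result was seen. The test of neighbouring probe sets was also reworded after its first outcome was seen, which changed its reading. The first form counted pairs of called neighbours more than once and gave a median of 1.68, which was read as excluding sequence differences; the reworded form leaves them open.

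Some control signals outside the comparisons stood above those of the mock arrays of the same variety. The 25S rRNA signal averaged 2851 in Moneymaker infected against 1048 in mock arrays, and the 17S rRNA signal 1047 against 358. In Mogeor they did not: 25S was 2258 and 3104 in infected against 3616 and 1561 in mock arrays, and 17S 889.9 and 1343 against 2029 and 577.9. The mean log2 ratio of 3′ to 5′ control probe sets was 0.942 against 0.361 in Moneymaker and 0.798 against 0.508 in Mogeor. The phenylpropanoid list differed in its infection effect between the varieties (camera adjusted p = 0.0449; adjusted p = 0.402 with an estimated correlation). It passed in 8 of 16 alternatives, and no single member passed over all probe sets. This interaction rests on the same mock arrays as the lower list values in Mogeor mock-treated roots, so they are not separate results.

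The infection calls go with the control ratio, which separates infected from mock arrays completely, and a difference in scale that depends on signal does not account for most of them, since 88.3% of the 1355 calls were made again in the same direction after quantile normalization. In a 2-group fit without genotype, the real split gave 855 calls and the highest of the other splits 324, so 1 of 35 splits, the real one itself, gave as many; this share of 0.029 is the smallest possible. The splits exchange arrays across the varieties, whose own split gave 124 calls. They also treat the 2 arrays of a group as separate samples, although the labels do not say whether they are. The splits can therefore not decide whether chance gave the calls. The real split is also the split by the mean control ratio. With the ratio as a covariate the effects of the called probe sets kept a median of 0.674 of their size (0.22 to 0.811 without each array), with 1243 in the same direction; their median size went from 0.56 to 0.35 and their median SE from 0.123 to 0.287, so the calls ended through both. RNA integrity and infection cannot be told apart for these calls, because no array breaks the link by the mean ratio. The ratios of actin, gapdh and ubiquitin taken singly did overlap between infected and mock arrays. A response to the fungus stays open as a hypothesis.

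The differences between varieties stood alike in mock and infected roots, and sequence differences under single probe sets may account for part of them. In 6 clusters with other probe sets, the others had a median log2 difference of 0.528 in the direction of the call (quartiles -0.383 and 2.01), against 2.8 for the called ones; the first form gave 1.68 (quartiles -0.109 and 3.61 over 8 called probe sets). In 2 clusters the others moved over 50% as far and in 3 under 25%, so sequence differences and differences in transcript level cannot be told apart here, with few clusters and mixed values. GAI and TIM10 have no such neighbours among the tested probe sets.

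Mogeor mock replicate 2 and Moneymaker infected replicate 1 lay between the varieties on the first component. Over the 61 probe sets called between varieties in mock roots, Moneymaker infected replicate 1 had a median position of -0.0193 (quartiles -0.154 and 0.0601) from its replicate at 0 to Mogeor at 1, which argues against a mixed or mislabelled array. Over the 58 called in infected roots, Mogeor mock replicate 2 had a median position of 0.912 (quartiles 0.737 and 1.08) from Moneymaker at 0 to its replicate at 1. A small admixture in that array stays open because of the spread between probe sets. Why both arrays stand apart on the component was not tested further.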

How the results depend on the processing

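The covariates, leaving out 2 arrays together, the crossed replicate block, the named-gene background and the lists without misplaced members were chosen after seeing the data. Apart from leaving out single arrays, 72 counts and correlations stayed within the limits set and 22 moved; the cause was not tested unless stated. For infection in Moneymaker (326) the count was 153 without a filter, 190 without trend, 904 with only the groups compared, 129 at a 2-fold minimum (by construction), 0 with the control ratio, 0 with the 25S signal and 23 without 2 arrays. The averaged effect (1355) gave 86 at a 2-fold minimum, 0 with either covariate and 1 without 2 arrays. In limma the covariates left 352 and 618 probe sets at an unadjusted p under 0.05 in Moneymaker and 423 and 1009 in the averaged effect. Infection in Mogeor (0) gave 1 with a crossed block. The genotype difference in mock roots (61) gave 27 with only the groups compared, 33 and 10 with the covariates and 320 without 2 arrays, and in infected roots (58) 31 with the lowest 50% left out, 33 and 102 with the covariates and 303 without 2 arrays. The correlation of infection effects (0.708) was 0.36 with the 25S signal and 0.504 without 2 arrays.

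Leaving out each array gave 0 to 509 for Moneymaker, 0 to 9 for Mogeor, 0 to 1552 for the averaged effect, 20 to 163 and 25 to 126 for the genotype differences in mock and infected roots, 0 to 0 for the interaction in limma (100 to 468 at an unadjusted p under 0.05) and 0.524 to 0.685 for the correlation. With the replicate number as a block the counts were 224, 0, 1239, 80, 53 and 0, in the order of the comparisons.

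With the control ratio LOC543813, DES and OPR3 turned to -0.21, -0.073 and -0.008 on the log2 scale in the averaged effect. Lists that turned direction were jasmonate, ethylene, defence and abscisic acid in Moneymaker (adjusted p = 0.0101, 0.0765, 0.0101 and 0.023), defence in Mogeor (0.827), and ethylene and defence in the averaged effect (0.552 and 0.0953). Of the named genes past the threshold, GAI passed in all alternatives in both treatments and TIM10 in those of infected roots; the 41 entries of the averaged effect passed in 6 to 14. The median change in the averaged effect went from -0.139 in the dimmest 20% of probe sets to 0.079 in the brightest. What signal over background limits was not tested, and detection calls were not used here.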

Other observations

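The mitochondrial import gene TIM10 and the DELLA gene GAI differed between the varieties more than they changed with infection. TIM10 had infection effects of -0.23 ± 0.20 (SE) in Moneymaker and -0.64 ± 0.20 in Mogeor, neither past the threshold in limma. Photosynthesis genes, listed as markers of shoot tissue, had a median genotype difference of -0.142 in mock and -0.0475 in infected roots. In limma 0 of 4 passed in any comparison (smallest adjusted p = 0.13 for infection in Moneymaker). A probe set without a gene name was picked after its values were seen. It had a signal of 438 ± 16 (SD, n = 2) in Moneymaker infected roots and 37.2 ± 39.1 in Moneymaker mock. In Mogeor it had 12.1 ± 10.1 in mock and 0.573 ± 0.657 in infected roots. These Mogeor means lay under the highest reporter signals, 18.8 and 23.6 on the mock and 11.3 and 20.6 on the infected arrays. The probe set passed for infection in Moneymaker (limma adjusted p = 0.0369) and between the varieties in infected roots (limma adjusted p = 0.00347). No probe set passed the interaction, so a response in Moneymaker alone is not shown.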
